A study of Mus musculus with 2 samples.

How the data were processed

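Chromatin from the lungs of mouse embryos at embryonic day 16.5 was immunoprecipitated with an antibody against histone H3 trimethylated at lysine 36 (H3K36me3) and sequenced (ChIP-seq). H3K36me3 is placed by the methyltransferase Setd2, which travels with elongating RNA polymerase II, so the mark lies over the bodies of transcribed genes. Per the labels, the 2 libraries are biological replicates from pools of male and female embryos of a C57BL/6 substrain, and the replicate 2 pool held 41 embryos. They form 1 group. The series as analysed here has no second tissue, stage or treatment, so the comparisons are between the replicates and between genes or regions within the tissue.

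The deposited data were 4 peak lists on mm10 (GRCm38). Per the accompanying text files, a list was called on each replicate alone, another on both replicates together (the pooled list), and the last, termed replicated peaks, was derived from those 3. The same text files show that the replicate 1 list was called against more control alignment files than the replicate 2 list. The aligner, the peak caller and the rule that made the replicated list are not given in the sources used here. Each peak has a fold enrichment over control, a linear ratio as deposited by the authors. Each also has a -log10 p and a -log10 q as deposited by the authors. The smallest -log10 p was between 2.01 and 2.03 in the 4 lists. The -log10 q reached down to 0.0679 in replicate 2, and 44.5% of its peaks had q under 0.05, against 96.6% in replicate 1, so the lists were limited by p and not by q. No read counts accompany the lists, so the sequencing depth of each library is unknown, and a base outside a peak is not shown to lack the mark. The peak scores were used only to describe, rank or filter peaks within a list.

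Every replicated peak was also in the pooled list. Of the 102412 replicated peaks, 54813 (53.5%) overlapped a peak of both replicates by at least 1 bp, 42790 overlapped replicate 1 alone, 2885 replicate 2 alone and 1924 neither. No pooled peak outside the replicated list overlapped both replicates by at least 50% of either peak. The replicated list therefore holds the pooled peaks found in both replicates by that rule plus others. The 53664 replicated peaks that met the rule were used as an alternative list, chosen after this was seen.

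Genes were taken from GENCODE M21 for GRCm38, leaving out pseudogenes, on chromosomes 1 to 19, X and Y (41890 genes, of which 21938 protein-coding). Chromosome lengths and bases came from the RefSeq copy of GRCm38.p6. The covered percent of a gene is the percent of bases between its annotated start and end that lie in peaks, and a gene was called marked where this was at least 10%. ChIP reads carry no strand, so coverage of overlapping genes cannot be assigned to one of them, and a version with only the genes that overlap no other gene was run. Some annotated gene bodies include rare long transcripts, which lowers the covered percent: the annotated body of Fgfr2 spans 2961 kb.

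Overlaps between lists and the share of peak bases in genes were compared with 1000 circular shifts of the peaks along each chromosome (one-sided permutation tests, smallest possible p = 0.001). The 3' side of the gene midpoint was compared with the 5' side, and exons with introns, in protein-coding marked genes of at least 5 kb by 100000 sign flips of the per-gene differences (two-sided permutation tests, smallest possible p = 1e-05). There were 27 gene lists: cell types and signalling of the lung (distal epithelium, airway epithelium, mesenchyme, smooth muscle, endothelium, morphogen signalling), other cells the sample could hold (immune, erythroid, cardiac), other tissues (neurons, liver, skeletal muscle, germ cells, kidney and intestine), general functions, gene families, Hox genes, imprinted genes and long non-coding RNAs. Each list's mean covered percent was placed among 10000 random lists of protein-coding genes of the same size, matched by decile of gene length (two-sided permutation p, smallest 0.0002, Benjamini-Hochberg adjusted over the 27 lists). The 140 genes of the lung lists were compared with the 100 genes of the other-tissue lists by permuting membership 100000 times within quintiles of gene length. Of the listed symbols, 1 (Ahsp) matched no gene. In all these tests genes or regions are the unit. They are not independent replicates, and the p-values describe these libraries. The values in the 2 replicates' own lists are the only measure of spread between libraries here, and they are given beside many of the results. The 2 lists also differ in peak number, q values and control files, so the gap between them is not biological spread alone.

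The lists, the threshold of 10%, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 3 members with the highest and 2 with the lowest covered percent of each list, 16 lung genes and regulators chosen in advance, the 10 protein-coding genes of at least 10 kb with the highest covered percent, the 5 of at least 10 kb with the largest difference between replicates in each direction (each replicate scaled by its mean covered percent, which favours heavily covered genes in the direction of replicate 2), the 5 strongest replicated peaks and the 5 longest stretches of peaks outside genes. Alternatives were a stricter -log10 q of at least 5, the pooled list, each replicate's own list (written as without the other replicate), joining peaks closer than 1 kb, other coverage and overlap limits, and genes that overlap no other gene.

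The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The functions were tested on simulated data. Of 2000 genes given simulated peaks, 100% were called marked and 0 other genes were. The overlap counts of 20000 peaks differed from those of bedtools 2.31.1 by 0 under each overlap rule. With no effect simulated, 6% of 300 random lists, 7.33% of 300 sets of symmetric differences and 3.67% of 300 random splits fell under 0.05, as did 7.5% of 40 overlaps of shifted lists and 0% of 40 genic shares of shifted lists.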

Results

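H3K36me3 ChIP-seq of embryonic day 16.5 mouse lung was available as 4 peak lists: replicate 1, replicate 2, both pooled, and the authors' replicated peaks. The lung at this stage holds distal and airway epithelium, mesenchyme, smooth muscle, endothelium and blood cells, which share each library. The replicate 1 list had 179894 peaks covering 71.1 Mb and the replicate 2 list had 79263 peaks covering 23.5 Mb. The pooled list had 139093 peaks (58.0 Mb) and the replicated list 102412 (49.5 Mb, 1.82% of chromosomes 1 to 19, X and Y). The median replicated peak was 364 bp wide with a fold enrichment of 3.75, by the authors' values. The depth of the libraries is unknown, and unless stated otherwise values refer to the replicated peaks and positions to mm10.

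The peaks of the 2 replicates overlapped more than shifted peaks did. Of the replicate 2 peaks, 83.2% overlapped a replicate 1 peak by at least 1 bp, and 32.7% of the replicate 1 peaks overlapped a replicate 2 peak. Shifted peaks gave means of 4.69% and 2.03% (one-sided permutation p = 0.001 for each, the smallest 1000 shifts can give). The 2 shares were 31.6% and 13.9% where at least 50% of both peaks had to overlap, and 61.1% and 49.4% with the same number of top peaks from each replicate. With the top 20000 peaks of each they were 44.2% and 37.3%. Of all bases covered in either list, 23.0% were covered in both, against 0.752% after shifting (permutation p = 0.001). At the stricter peak threshold, which left 644 replicate 2 peaks, 2.10% of these bases were covered in both and 1.49% of the replicate 1 peaks overlapped a replicate 2 peak. At the gene level, the 3133 protein-coding genes marked in replicate 2 included 3125 of the 6988 marked in replicate 1. Across 21938 protein-coding genes, which are not independent replicates, the covered percent in the 2 replicates had a Spearman rho of 0.905 (95% interval 0.902 to 0.908). The rho was 0.861 over the 11156 genes with a peak in either replicate, and 0.254 over all genes at the stricter peak threshold. The genes of at least 10 kb that leaned most to replicate 1 after scaling were Ska3, Arv1, Thop1, Cc2d1a and Fbxo22. Ska3, a kinetochore gene, was covered over 47.4% of its body in replicate 1 and 2.18% in replicate 2. The genes picked for replicate 2 by the same scaling were Zfp110, Zfp606, Hjurp, Polrmt and Zfp68. All 5 were covered more in replicate 1, and since coverage cannot exceed 100% the scaling places any gene so heavily covered in replicate 2 on that side. Zfp110 (chromosome 7, 12834761 to 12850577) was covered over 87.5% in replicate 1 and 77% in replicate 2, and Polrmt, the mitochondrial RNA polymerase, over 69.8% and 62.6%.

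Of the pooled peaks, 36681 (26.4%) were missing from the replicated list. They were narrower, with a median width of 207 bp against 364 bp, and weaker, with a median fold enrichment of 3.04 against 3.75. They lay in genes about as often as the others, with 95% of their bases in gene bodies against 95.8%. With -log10 q of at least 5, 0.779% of the pooled peaks were missing.

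The mark lay over gene bodies. Of the replicated peak bases, 95.8% were inside annotated genes, against a mean of 46.9% and a maximum of 51.3% for shifted peaks (one-sided permutation p = 0.001). The replicates' own lists gave 95.4% (replicate 1) and 95.7% (replicate 2). Exons held 29.7% of the peak bases and make up 4.34% of the genome, and introns held 66.1% and make up 39.6%. The 1 kb upstream of genes held 0.112%, below every shift, whose lowest value was 0.803% (one-sided permutation p = 0.001). Only 3772 replicated peaks (3.68%) lay outside every annotated gene, and 3420 of these (90.7%) were within 5 kb downstream of the 3' end of a protein-coding gene.

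By the 10% limit, 5628 of 21938 protein-coding genes (25.7%) were marked, 6988 in replicate 1 and 3133 in replicate 2. Any replicated peak was present in 9625 genes. The most fully covered genes of at least 10 kb were Zfp110 (85.5%), Zfp606 (82.4%), Ddx39b (79.1%), Prrc2a (78.7%), Cherp (78.6%), Fasn (78.4%), Leng8 (77.9%), Eif4g2 (77.7%), Chd4 (76.9%) and Ddx17 (76.6%). Ddx39b and Ddx17 encode RNA helicases, Fasn the fatty acid synthase, Eif4g2 a translation initiation factor and Chd4 a chromatin remodeller. All 10 were also covered in each replicate's own list, Fasn over 76.0% in replicate 1 and 46.8% in replicate 2. Counts of marked genes depended on the list and the limit: 2314 genes were marked at the stricter peak threshold and 573 had at least 50% of the body covered.

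Within marked genes the mark rose from the 5' end to the 3' end. In 5104 protein-coding genes of at least 5 kb, peaks covered on average 17.5% of the bases on the 5' side of the gene midpoint and 39.4% of those on the 3' side, a difference of 21.9 percentage points (standard error over genes 0.303). The 3' side was higher in 86.3% of the genes (two-sided sign-flip permutation p = 1e-05, the smallest the test can give). In the same genes the difference was 24.2 points in replicate 1 and 10.4 points in replicate 2. In 20 equal bins, coverage went from 0.994% in the first bin to 43.3% in bin 18, and was 35.6% in the last.

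**Figure D1:**
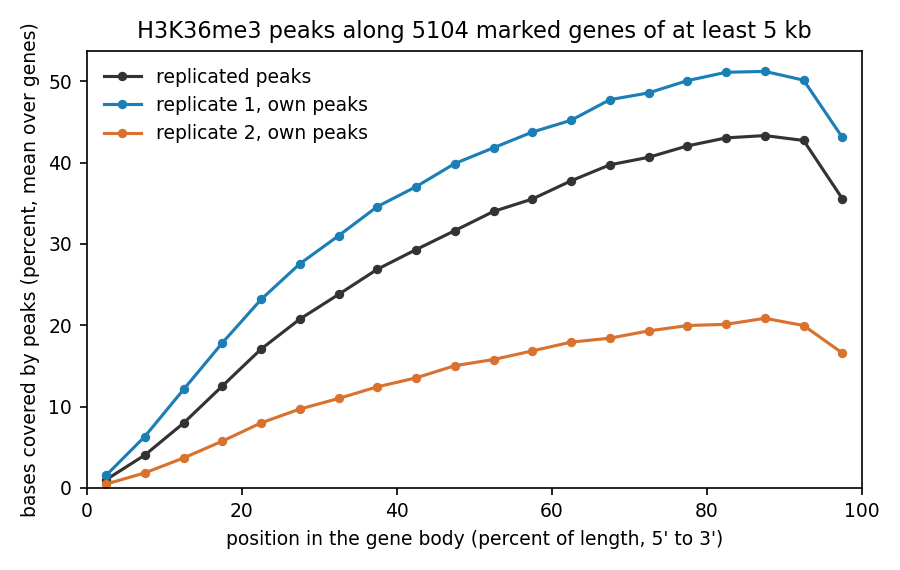
Mean percent of bases covered by peaks (vertical axis) along the gene body in 20 bins from the 5' end to the 3' end (horizontal axis, percent of gene length), over the 5104 marked genes of at least 5 kb, for the replicated peaks and each replicate's own peaks. All 3 lines rise from under 2% in the first bin to their highest value in bin 18 (43.3%, 51.2% and 20.9%) and fall in the last bin.

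Exons of marked genes were covered more than their introns. In 5095 of these genes that have introns, 39.9% of exonic bases and 25.1% of intronic bases lay in peaks, a difference of 14.8 points (standard error over genes 0.274), and exons were higher in 79.0% of genes (two-sided sign-flip permutation p = 1e-05). The difference was 14.7 points in replicate 1 and 7.80 points in replicate 2. With the first exon and first intron left out it was 10.6 points. The comparison was not matched for position along the gene, and the last exon was kept. It therefore does not separate exons as such from the rise toward the 3' end.

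The genes most covered as groups were those that dividing and growing cells use in general. Of the cell cycle genes, 22 of 23 were marked, with a mean of 42.5% of the gene body covered against 10.5% expected from length-matched genes. Cdk1, the mitotic kinase, was covered over 69.7%, the topoisomerase gene Top2a over 65.3% and Mcm2, a subunit of the replicative helicase, over 64.8%. The exception was Pcna, the sliding clamp of DNA replication, at 6.57%, and Rrm2 was next lowest at 13.7%. Of the transcription and splicing genes, 19 of 20 were marked (mean 43.7%, expected 10.4%). They were led by the splicing factor genes Prpf8 (75.0%) and Snrnp200 (69.7%) and by the translation initiation gene Eif4g1 (58.2%), with the X-linked Mediator gene Med12 lowest at 8.98% and Srsf1 at 20.8%. Prpf8 lay at chromosome 11, 75486816 to 75509449. In replicate 1 and replicate 2 the cell cycle list had means of 50.9% and 18.1% and the transcription and splicing list 49.4% and 24.5%. Each of these lists had an adjusted p = 0.00049 against 10000 random lists (two-sided permutation). Top2a, Eif4g1, Med12 and Srsf1 overlap other annotated genes.

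Genes of the protein synthesis and degradation machinery were also covered above length-matched genes. Of 81 ribosomal protein genes, 62 were marked (mean 31.9%, expected 5.09%), among them Rps5 (72.6%), Rps3 (71.0%) and Rpl5 (68.2%). Of the 81 genes, 67 had a replicated peak. Those with none included Rpl3l and Rpl39l, paralogs with tissue-restricted expression, and, named after their values were seen, the generally used Rps27, Rplp1, Rpl41 and Rpl36. Of 39 proteasome genes, 30 were marked (mean 28.1%, expected 9.35%), led by Psmc1 (64.7%), Psmd3 (58.0%) and Psmd7 (55.5%). Psma8, the testis subunit, and the X-linked Psmd10 had no replicated peak, though Psmd10 was covered over 7.24% in replicate 1 and 7.43% in replicate 2. Of 19 genes on the list for writers, erasers and readers of H3K36 methylation, 14 were marked (mean 24.2%, expected 7.30%). They included the demethylase gene Kdm4a (67.5%), the mismatch repair gene Msh6 (37.9%) and Setd2 itself (25.2%). The list as fixed also held the maintenance DNA methyltransferase gene Dnmt1 (52.5%), which acts on DNA and not on H3K36. The de novo methyltransferase gene Dnmt3b (2.20%) and Phf19 (0%) were lowest. The replicate 1 and replicate 2 means were 35.9% and 17.5% for ribosomal protein genes, 34.6% and 14.5% for proteasome genes, and 31.0% and 11.8% for the H3K36 list. These 3 lists also had an adjusted p = 0.00049 (two-sided permutation), and passed in each replicate's own list (adjusted permutation p = 0.00045 in replicate 1 and 0.00054 in replicate 2). Rps3, Rpl5, Psmd3, Kdm4a, Dnmt1, Msh6 and Setd2 overlap other annotated genes.

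Genes of the lung's own cell types were covered unevenly. In the mesenchyme list 8 of 30 genes were marked, with a mean of 9.14% (expected 7.2%, adjusted two-sided permutation p = 0.409). The Hedgehog receptor gene Ptch1 (48.5%; chromosome 13, 63508328 to 63573598), the fibronectin gene Fn1 (47.8%; chromosome 1, 71585520 to 71653200) and the collagen gene Col6a1 (37.5%) were highest. The list had 18 marked genes in replicate 1 (mean 16.1%), where it passed the threshold (adjusted permutation p = 0.0375), and 4 in replicate 2 (mean 4.43%, adjusted permutation p = 0.398). The T-box gene Tbx4 was covered over 12.4%, with 21.6% in replicate 1 and 5.45% in replicate 2. The platelet-derived growth factor receptor gene Pdgfra was at 9.48%, Fgf10 at 0.264%, and Foxf1, Meox2 and Wnt2 at 0%. In the morphogen signalling list 11 of 24 genes were marked (mean 12.6%, expected 7.99%, adjusted permutation p = 0.120). Vegfa (chromosome 17, 46016993 to 46032369), a growth factor for blood vessels, was covered over 43.9%, the Wnt pathway genes Axin2 and Ctnnb1 over 33.5% and 31.0%, and Wnt7b and Etv4 over 0%. The list's mean was 15.9% in replicate 1 and 5.56% in replicate 2. Ptch1, Fn1, Pdgfra, Axin2 and Ctnnb1 overlap other annotated genes.

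Airway genes were below length-matched genes, and the distal epithelium list lay on the same side close to the threshold. In the distal epithelium list 4 of 32 genes were marked, with a mean of 3.46% (expected 8.13%, adjusted two-sided permutation p = 0.0535), and of 5.12% in replicate 1 and 1.86% in replicate 2. This list passed with peaks closer than 1 kb joined (adjusted permutation p = 0.034) and with the peaks found in both replicates (adjusted permutation p = 0.0446), but not at the stricter threshold (adjusted permutation p = 0.166), in replicate 2 (adjusted permutation p = 0.137) or among the 21 genes that overlap no other gene (4.20% against 6.32% expected, adjusted permutation p = 0.572). Lpcat1 (chromosome 13, 73467197 to 73516422), an enzyme of surfactant lipid synthesis, was covered over 26.3%, the keratin gene Krt18 over 21.2% and Ager, a marker of alveolar type I cells, over 21.1%. Krt18 and Ager are short (3.848 and 3.075 kb), and peaks running in from a neighbouring gene were not tested for. The lung transcription factor gene Nkx2-1, the distal tip gene Sox9, the surfactant gene Sftpc, Lamp3 and Ehf had no replicated peak. All cell types share each library and the depth is unknown. The absence of a peak therefore does not show that a gene lacks the mark in the cells that use it, here or in the cell type lists below. Nkx2-1 was covered over 3.53% in replicate 1, and the surfactant gene Sftpb over 2.34% by replicated peaks and 9.0% in replicate 1. In the airway list 0 of 18 genes were marked and the mean was 0.0786% (expected 7.27%, adjusted permutation p = 0.00166), with 0.195% in replicate 1 and 0.0659% in replicate 2. Rfx3 was its only gene with a replicated peak, at 1.42%, while Sox2, Scgb1a1, Foxj1, Dnah5 and Trp63 had none. Among the 10 airway genes that overlap no other gene the mean was 0% against 6.13% expected, which did not pass (adjusted permutation p = 0.0836). A mean of 0% is the lowest possible, so no coverage below expected could have passed with 10 genes, and this check cannot decide.

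Endothelial genes were covered less than length-matched genes, and the smooth muscle list did not pass the test. In the endothelium list 2 of 21 genes were marked, Eng (13.4%) and Ets1 (10.2%), and the mean was 1.48% (expected 6.62%, adjusted two-sided permutation p = 0.0278), with 2.90% in replicate 1 and 0.348% in replicate 2. The endothelial receptor gene Kdr was covered over 1.87% and Pecam1 over 0.438%, and Erg and Vwf had no replicated peak. The endothelium list did not pass at the stricter peak threshold (0.375% against 2.46% expected, adjusted permutation p = 0.105) or among the 15 genes that overlap no other gene (0.48% against 5.2% expected, adjusted permutation p = 0.0677). In the smooth muscle list 3 of 15 genes were marked, the tropomyosin gene Tpm1 (35.1%), Tagln (17.2%) and Notch3 (13.6%). Its mean was 5.54% (expected 8.24%, adjusted permutation p = 0.489), with 8.14% in replicate 1, 2.54% in replicate 2, Acta2 at 4.20% and Myh11 and Synpo2 at 0%. Eng, Ets1, Tagln and Notch3 overlap other annotated genes.

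Of other cells the sample could hold, immune genes had a mean of 2.26% with 1 of 17 marked (expected 8.12%, adjusted two-sided permutation p = 0.0602), and of 5.06% in replicate 1 and 1.89% in replicate 2. That gene was Cd68 (26.5%), a macrophage gene of 1.94 kb, followed by Fcer1g (8.01%) and Csf1r (3.86%), while Ptprc and Adgre1 had no replicated peak. Peaks outside genes lay mostly within 5 kb downstream of a 3' end. Coverage of a gene as short as Cd68 was not separated from such peaks of a neighbouring gene. Erythroid genes (mean 0.168%, 0 of 13 marked, adjusted permutation p = 0.0114) and cardiac genes (mean 0%, 0 of 14 marked, adjusted permutation p = 0.00166) were below length-matched genes. Neither passed at the stricter peak threshold (both 0%, against 2.73% and 3.42% expected, adjusted permutation p = 0.0908 and 0.0792). Neither passed among the 10 and 5 genes that overlap no other gene (0.124% against 5.99% and 0% against 6.42% expected, adjusted permutation p = 0.0963 and 0.471). A mean of 0% is the lowest possible, so where a list stood at 0% in these checks no coverage below expected could have passed.

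Genes of other tissues were close to free of peaks. No gene was marked among 20 each of neurons, liver, skeletal muscle and germ cells, whose means were 0%, 0.0475%, 0% and 0.0964% (adjusted two-sided permutation p = 0.00049 for each). Nrxn1, Syt1, Cps1, Hnf4a, Ryr1, Pax7, Tex14 and Sycp1 had no replicated peak, and Hnf1a was covered over 0.950% and Dazl over 1.26%. The kidney and intestine list had 1 of 20 marked (mean 1.11%, adjusted permutation p = 0.00288): Slc5a2 (21.1%), which overlaps another gene. Among the 7, 12 and 9 genes that overlap no other gene, the neuron, skeletal muscle and kidney and intestine lists had means of 0% against 5.42%, 5.53% and 7.07% expected, and did not pass (adjusted permutation p = 0.0888, 0.0677 and 0.0501). A mean of 0% is the lowest possible, so no coverage below expected could have passed with so few genes, and this check cannot decide. The 140 lung genes had a mean of 5.74% with 28 marked, and the 100 genes of other tissues a mean of 0.251% with 1 marked. The difference of 5.49 points (two-sided permutation p = 1e-05 within length quintiles) was 8.31 points in replicate 1 and 2.56 points in replicate 2. Of the lung genes, 43 were marked in replicate 1 and 12 in replicate 2, and of the others 1 and 0. The lung lists contributed unevenly. The morphogen signalling and mesenchyme lists had means of 12.6% and 9.14%, and the endothelium list 1.48%. The airway list, at 0.0786%, lay within the range of the other-tissue lists, so the difference does not hold for every lung cell type. No lung list passed above length-matched genes with the replicated peaks. The difference therefore rests on the low coverage of the other-tissue lists. It does not show lung genes covered above genes in general. Of 1418 olfactory and vomeronasal receptor genes, 0 had a replicated peak (expected mean 9.11%, adjusted permutation p = 0.00049).

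**Figure D2:**
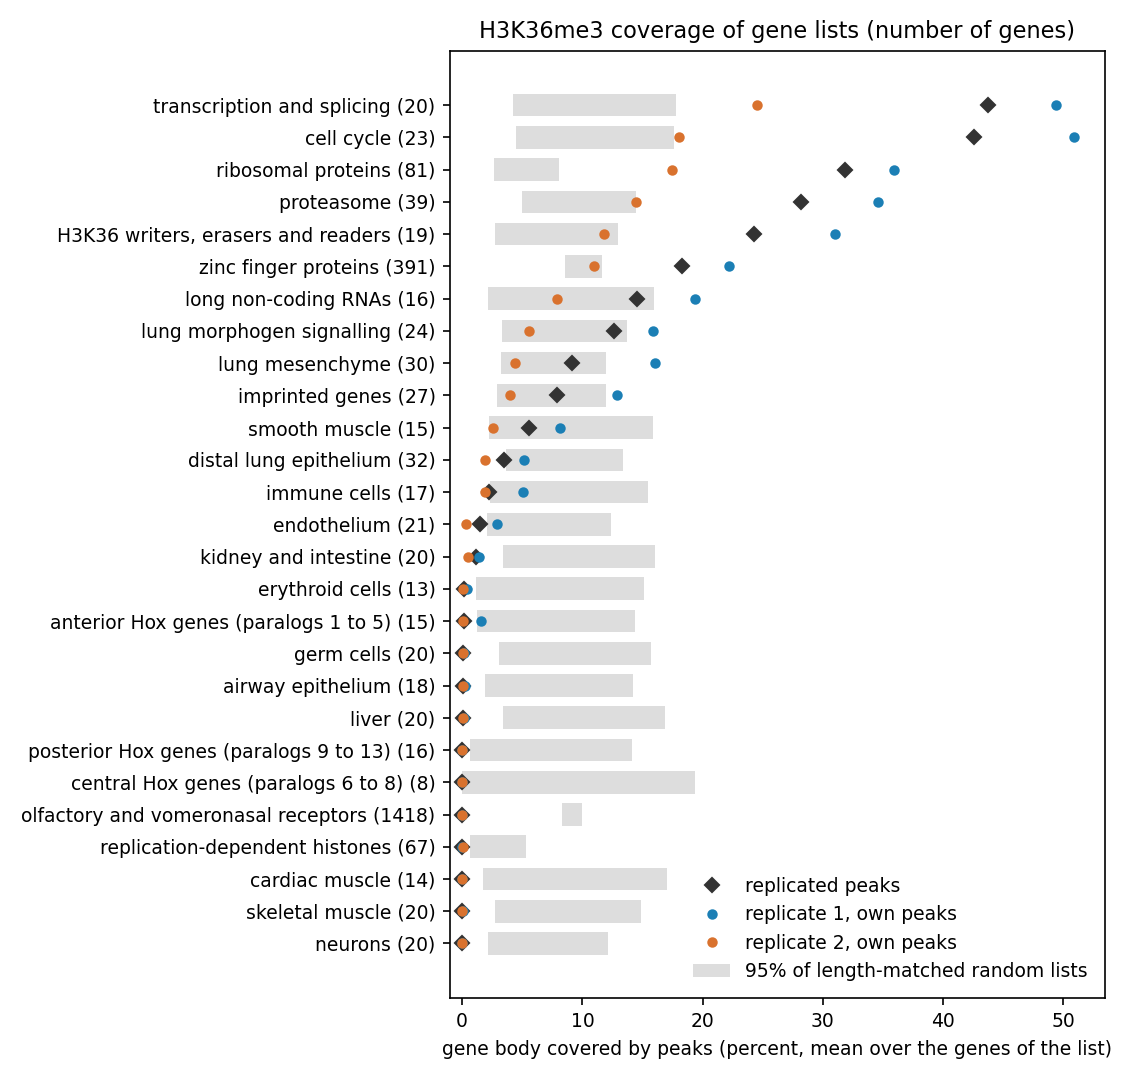
Mean percent of the gene body covered by peaks (horizontal axis) for each of 27 gene lists, with the number of genes in parentheses, from the replicated peaks (diamonds) and each replicate's own peaks (circles). Grey bars span 95% of 10000 length-matched random lists scored with the replicated peaks, so they are the reference for the diamonds alone. The transcription, cell cycle, ribosomal, proteasome, H3K36 and zinc finger lists lie above their bars.

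Zinc finger genes were covered more than length-matched genes, and histone genes and the anterior and posterior Hox genes less. Of 391 zinc finger protein genes, 212 were marked (mean 18.3%, expected 10.1%, adjusted two-sided permutation p = 0.00049), with 252 marked in replicate 1 (mean 22.2%) and 152 in replicate 2 (mean 10.9%). Zfp869 was covered over 90.3% of its body and over 80.5% in replicate 2, while the long genes Zfp804b and Zfp385b had no replicated peak. Replication-dependent histone genes, whose main transcripts lack introns and poly(A) tails, had 0 of 67 marked and no replicated peak (expected mean 2.64%, adjusted permutation p = 0.0027), including in Hist1h2be, Hist1h2bc and Hist1h1d. The histone list did not pass at the stricter peak threshold (0% against 0.874% expected, adjusted permutation p = 0.166) or among the 43 genes that overlap no other gene (0% against 1.57% expected, adjusted permutation p = 0.145). A mean of 0% is the lowest possible, so no coverage below expected could have passed in these checks. Of the Hox genes, paralogs 1 to 5 had a mean of 0.137%, from Hoxb3 alone (2.05%), and paralogs 6 to 8 and 9 to 13 had no replicated peak. The anterior minus posterior difference was 0.137 points (two-sided permutation p = 0.482), and 1.59 points in replicate 1 (permutation p = 0.0176). The anterior and posterior lists were below length-matched genes (adjusted permutation p = 0.00877 and 0.0278), and the central list of 8 genes did not pass (adjusted permutation p = 0.136). At the stricter peak threshold neither the anterior nor the posterior list passed (both 0%, against 2.59% and 2.70% expected, adjusted permutation p = 0.0997 and 0.33). The posterior list, with a mean of 0% throughout, also did not pass in replicate 2's own peaks (adjusted permutation p = 0.0668), with the peaks found in both replicates (adjusted permutation p = 0.0931) or among the 10 genes that overlap no other gene (adjusted permutation p = 0.444). Where a Hox list at 0%, the lowest possible mean, did not pass, no coverage below expected could have passed.

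Imprinted genes had 8 of 27 marked (mean 7.90%, expected 6.97%, adjusted two-sided permutation p = 0.651), with 11 marked in replicate 1 (mean 12.9%) and 2 in replicate 2 (mean 3.94%). Nnat (58.4%), Igf2r (28.8%) and Impact (26.9%) were highest and Snrpn and Usp29 had no replicated peak. All 5 overlap other annotated genes, so the coverage cannot be assigned to them alone. Of 16 long non-coding RNA genes, 6 were marked (mean 14.6%, expected 8.14%, adjusted permutation p = 0.120), with 8 in replicate 1 (mean 19.4%) and 3 in replicate 2 (mean 7.88%). Mir17hg, the host of a microRNA cluster, was covered over 62.9%, Tug1 over 52.9% and Gas5, a host of small nucleolar RNAs, over 43.2%. Gas5 was covered over 54.3% in replicate 1 and 8.09% in replicate 2, where it was not marked. Neat1 and Miat had no replicated peak. All 16 overlap another annotated gene.

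By the 10% limit, marking was most frequent in genes of intermediate length. Of genes of 10 to 30 kb, 36.8% were marked (exact 95% binomial interval 35.7 to 38.0%, n = 6502), against 3.65% of genes under 2 kb (2.78 to 4.70%, n = 1588) and 7.78% of genes over 100 kb (6.76 to 8.91%, n = 2492). The same 3 classes gave 43.2%, 4.91% and 14.0% in replicate 1 and 22.7%, 1.89% and 2.01% in replicate 2. These intervals cover counting error only. Marked is a share of the body, so a longer gene needs more bases in peaks to be called marked. Genes with any peak were not counted per length class. The histone and receptor genes, none of which had a replicated peak, were not left out. Gene length as such was therefore not separated from the definition of marked or from the kinds of genes in each class.

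**Figure D3:**
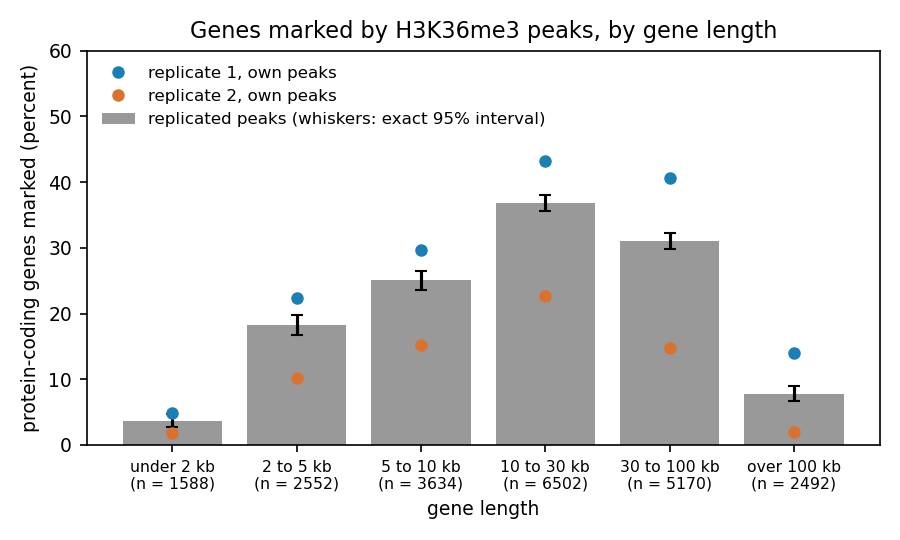
Percent of protein-coding genes marked (vertical axis) in 6 classes of gene length (horizontal axis, n per class below), with grey bars for the replicated peaks, whiskers for the exact 95% binomial interval and circles for each replicate's own peaks. In all 3 lists the class of 10 to 30 kb is highest (36.8% for the replicated peaks).

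Genes on the X chromosome were marked less often than those on any autosome. On the X, 35 of 948 protein-coding genes were marked (3.69%), against 20.4 to 33.6% on the 19 autosomes (median 26.5%). The X value was 8.65% in replicate 1, where autosomes ranged from 25.8 to 41.2%, and 1.27% in replicate 2, where they ranged from 10.9 to 18.6%. On the Y chromosome 0 of 183 genes were marked. The pools held both sexes.

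**Figure D4:**
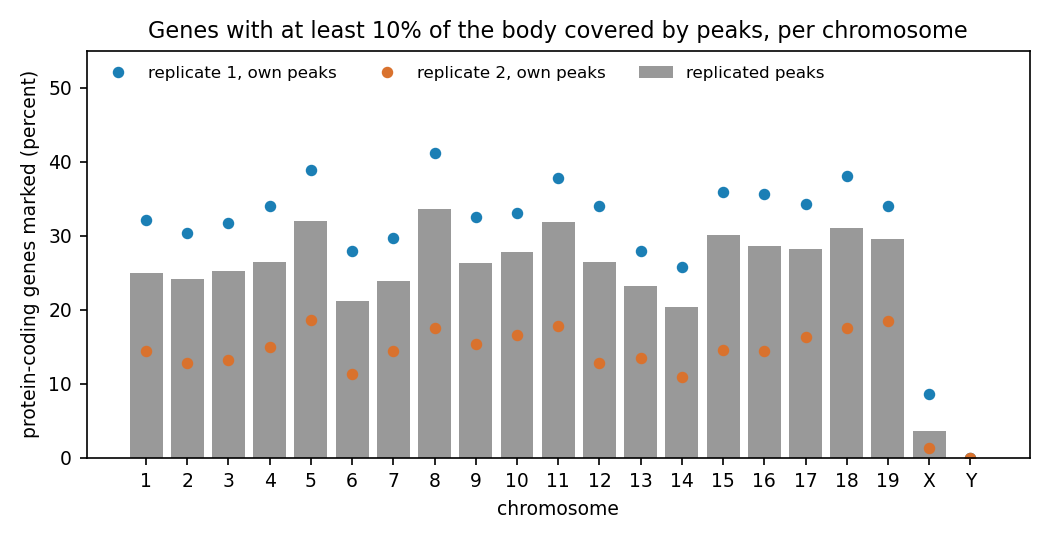
Percent of protein-coding genes with at least 10% of the body in peaks (vertical axis) per chromosome (horizontal axis), with bars for the replicated peaks and circles for each replicate's own peaks. The X bar stands at 3.69%, below the lowest autosome at 20.4%, and the Y has none.

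The 5 strongest replicated peaks by the authors' fold enrichment lay in or near zinc finger genes in 3 cases. The highest (21.4) was at 33991 to 36089 of an unlocalised chromosome 4 scaffold, which was not annotated here. The others were at chromosome 7, 12809238 to 12811646 (18.0, wholly in an exon of Zfp329); chromosome 7, 30160675 to 30164073 (16.3, 2805 of 3399 bases in Zfp146); chromosome 15, 76171735 to 76182006 (16.3, 10032 of 10272 bases in exons of the cytoskeletal linker gene Plec); and chromosome 7, 12488527 to 12492942 (15.9, in Zfp606, 866 of 4416 bases exonic). The longest stretch of peaks outside genes, 8.79 kb at chromosome 7, 30151675 to 30160465, ended 0.803 kb from Zfp146. The next 4, of 6.59 kb on chromosome 8, 6.21 kb on chromosome 14, 6.07 kb on chromosome 7 and 5.26 kb on chromosome 10, lay nearest to Asah1 (0.048 kb), Bmpr1a (0.069 kb), Zfp619 (40.3 kb) and Hcfc2 (0.435 kb).

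**Figure D5:**
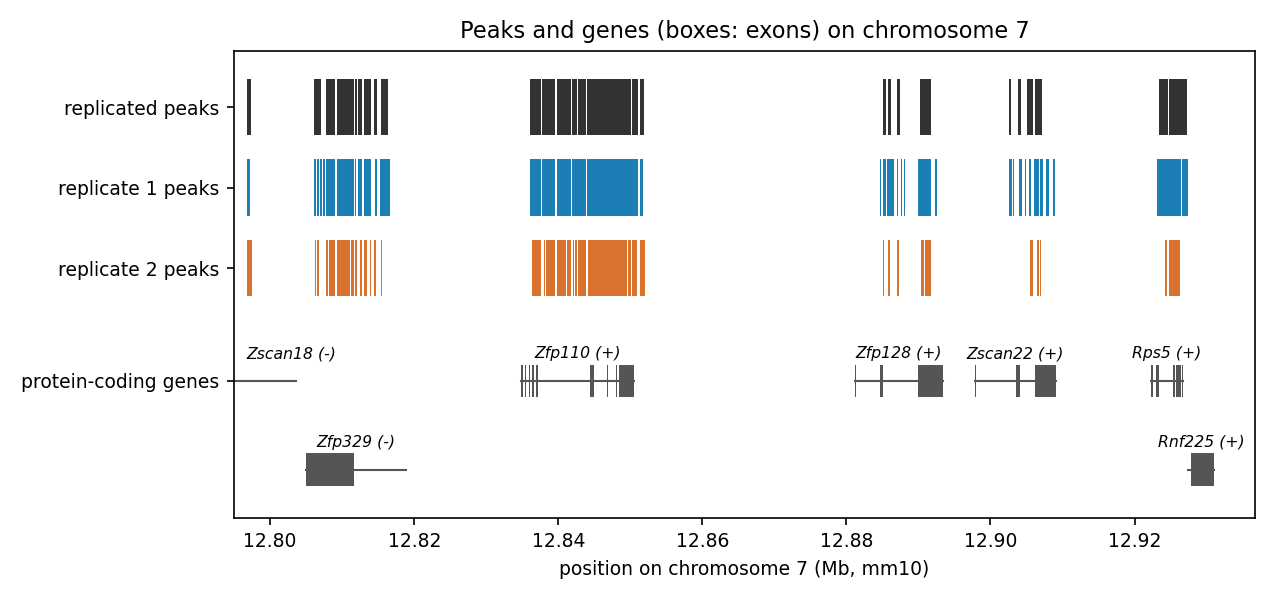
Peaks of the replicated list and of each replicate (coloured blocks) above the protein-coding genes (lines, with boxes for exons and strand in parentheses) along chromosome 7 in mm10 (horizontal axis, Mb). Blocks fill most of Zfp110 (85.5% covered), Zfp329 (57.2%) and Rps5 (72.6%), with none in Rnf225 beside Rps5.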

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

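The tests of gene content and of read number on the X, the share of strongest peaks predicted from GC content, the coverage of broadly used genes in replicate 2, and the reading of the test on cell type lists were chosen after the results they bear on had been seen.

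Outside the chromosomes used in the comparisons, 8 replicated peaks lay on unplaced or unlocalised scaffolds, and they stand here as a signal in sequences left out of the gene comparisons. The report counts them in the list and gives the strongest. The strongest had a fold enrichment of 21.4, above every peak on the chromosomes, and 6 of them were found in both replicates by the rule of at least 50% of either peak.

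Genes on the X chromosome were marked at 3.69%, against a median of 26.5% on autosomes. Gene length is argued against as the cause: the X genes had a mean covered percent of 1.24, and length-matched autosomal lists had a mean of 7.56 (two-sided permutation p = 0.0002, the smallest possible). A shortage of broadly expressed genes on the X is argued against as the whole cause, since the 6 X-linked members of the general lists had a mean of 1.5% and the 176 autosomal members of the same lists 34% (permutation p = 3e-05). Fewer reads from the X, which has a lower copy number in a pool of both sexes and is silenced on one copy in females, may hold peaks under the calling threshold: the ratio of X to autosomal percent marked was 0.0872 in replicate 2, 0.139 in the replicated list and 0.254 in replicate 1. That order would also follow from less H3K36me3 per X gene, and no biological explanation was tested, since the samples form 1 group.

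The strongest peaks lay in zinc finger genes more often than peaks in general: 163 of the 1000 strongest (16.3%) did, against 2.15% of all replicated peaks, and they fell in 99 different zinc finger genes. Reads shared between paralogs are argued against, since a median of 98.2% of the 32-base words in these peaks occur once in the genome, against 99% in the other strongest peaks. The read length and the treatment of reads with several matches are not given in the sources used here. GC content is argued against too: after matching on it, 95.6% of the difference in mean fold enrichment was left, and it predicted 2.34% of the strongest peaks in zinc finger genes. A hypothesis that stays open is a chromatin state of these genes that differs from other transcribed genes, for which no biological comparison was available.

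Replicate 2 had 79263 peaks and replicate 1 had 179894. A different cell make-up of the pools is argued against as the whole cause. The 140 genes of the ribosomal, proteasome, and transcription and splicing lists are broadly used as a group. They kept 47.1% of their replicate 1 coverage in replicate 2 (95% bootstrap interval over genes 43.6 to 50.5%), and 123 of them were covered less and 4 more. The tissue-restricted Psma8, Rpl3l and Rpl39l are among the 140, but had no peak in either replicate and so do not change this share. A lower sensitivity of the replicate 2 list is a candidate explanation. Replicate 2 peaks overlapped 75.5% of the strongest 10% of replicate 1 peaks by -log10 p and 14.1% of the weakest 10%, rising over each of the 10 classes. This overlap was counted from 1 bp and was not matched on peak width. The rise therefore cannot by itself tell lower sensitivity from other causes of a shorter list. The pooled list was shorter than the replicate 1 list (139093 peaks, 58.0 against 71.1 Mb, median fold enrichment 3.52 against 3.74). Fewer replicate 2 reads alone would not shorten a pooled list called the same way. This argues against depth as the only source, though the calling settings are not given. Enrichment and control files could not be told apart. Whether cell make-up adds to the difference in cell type genes stayed open: given replicate 1 coverage, the lowest adjusted permutation p over the cell type lists was 0.168 (mesenchyme, 4.93% in replicate 2 against 6.31% expected). A lowest p of at least 0.05 had been set in advance as the outcome against it and was met, but after the result was seen that bound was judged a poor one, since the random lists were wide (0.505 to 2.43% for endothelium, with 0.609% observed and 1.3% expected).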

How the results depend on the processing

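The direction and the side of the threshold held for the replicate overlap, the share of peak bases in genes, the 3' against 5' difference, the exon against intron difference and the lung against other-tissue difference under every alternative run. A pair of alternatives was chosen after seeing the data: the replicated peaks found in both replicates, and shifts that leave out assembly gaps. The number of lists above length-matched genes stayed between 5 and 7. The 5 came from the genes that overlap no other gene, where lists with fewer than 5 such genes were not tested. These were the H3K36, anterior Hox, central Hox and long non-coding RNA lists. Where values moved, the cause was not tested unless the setting itself (fewer peaks or genes) gives it. With -log10 q of at least 5, the peaks per list were 21706 (pooled), 21537 (replicated), 39482 (replicate 1) and 644 (replicate 2), 0.779% of pooled peaks were missing from the replicated list, 2314 genes were marked, 7 lists were below length-matched genes in place of 13, the class of 10 to 30 kb exceeded the shortest and the longest class by 16.9 and 17.0 points, the Spearman rho between replicates fell to 0.254 and the X minus autosome value was -10.1 points. Joining peaks closer than 1 kb left 45752, 40206, 56508 and 40982 peaks in the same order of lists and a rho of 0.901. The rho was 0.940 for genes of at least 10 kb and 0.910 with the same number of top peaks. Marked genes numbered 9625 with any covered base, 2853 at 25%, 573 at 50% and 2640 among genes that overlap no other gene, where 3 lists were below length-matched genes. At 25% coverage the length differences were 18.5 and 20.2 points. Taking 1 replicate's own list in turn gave 3133 to 6988 marked genes, an anterior minus posterior Hox difference of 0.0626 to 1.59 points (past the threshold in replicate 1 alone), length differences of 20.8 to 38.3 and 20.7 to 29.2 points, and X minus autosome values of -25.4 to -13.3 points. The direction turned for lists that had not passed with the replicated peaks: mesenchyme minus expected was -0.517 points at the stricter threshold, and imprinted genes minus expected was -2.92 points among genes that overlap no other gene. For single lists, 17 calls were lost and 3 gained over all settings, most of the losses with fewer peaks or fewer genes. Some lists that lost a call stood at 0%, the lowest possible mean, where no coverage below expected could have passed. Unknown depth limits every statement that a gene had no peak.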

Other observations

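The comparisons of single-exon genes, gene types and replicate 2 given replicate 1 were chosen after the results of the report had been seen.

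Single-exon protein-coding genes were covered less than length-matched genes with several exons. Leaving out histone and receptor genes, 64 of 1222 (5.24%) were marked, with a mean covered percent of 2.05 against 4.12 in the length-matched genes (95% of random lists 3.51 to 4.76, two-sided permutation p = 0.0002). The mean was 2.75 against 5.43 in replicate 1 and 0.938 against 1.76 in replicate 2 (permutation p = 0.0002 in each). Among genes that overlap no other gene, 20 of 4247 lincRNA genes (0.471%) and 2640 of 12509 protein-coding genes (21.1%) were marked. Unlike the single-exon comparison, this one was not matched on gene length, so length was not separated from gene type.

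In marked zinc finger genes, 52.1% of exonic bases and 21.6% of intronic bases lay in peaks (212 genes). Position along the gene was not matched here either. Given their coverage in replicate 1, zinc finger genes were covered more in replicate 2 than other genes, 13.5% against 9.93% expected (adjusted two-sided permutation p = 0.0028 over the lists so compared). Ribosomal protein genes were as well, 19.6% against 16.1% expected (adjusted permutation p = 0.0056). The matching was on covered percent and not on peak strength. Replicated peaks in zinc finger genes had a mean fold enrichment of 4.43, against 3.86 for other peaks in protein-coding genes. Stronger replicate 1 peaks were overlapped more often by replicate 2, so peak strength was not separated from gene family.

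On the X chromosome, replicate 1 alone covered several broadly expressed genes that the replicated peaks left out: Rpl39 over 25.5%, Rpl10 over 13.7% and Rpl36a over 10.8%, while Rps4x had no peak in replicate 1 and was covered over 4.58% in replicate 2.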
